A study of Arabidopsis thaliana with 5 samples.

How the data were processed

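The assay was chromatin immunoprecipitation followed by sequencing of eH3.3, a form of histone H3.3 pulled down with beads against the FLAG tag, in Arabidopsis thaliana plantlets aged 2.5 weeks. Per the labels, the 5 samples were 2 wild-type immunoprecipitates, 2 immunoprecipitates from the atrx-1 mutant and 1 wild-type input. The input was not analysed here. Nothing in the labels says whether the 2 samples of a genotype came from separately grown plants.

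The authors deposited 1 table of positions about the width of a nucleosome (200 bp each), with 1 track per genotype. Per the submitters' processing notes, FastQC, Trimmomatic, Bowtie and MACS2 were used and reads were placed on the TAIR10 build. Versions, the tool that wrote the table, the smoothing, the read extension and the scaling target are not given in the sources used here. Per the file headers, the table gives for each track a signal at its own summit and a signal at a common point. The signal is never negative and is a scaled coverage, with the 2 tracks scaled by the authors to similar totals (mean summit signal 322 and 308). The log2 columns deposited by the authors are folds between the tracks, and the false discovery rate columns are the authors' q-values. Within 0.01, and where both values are above 0, the deposited point fold equals the ratio of the point values at 100% of positions, but the deposited summit fold equals the ratio of the summit values at only 71.8%, and it departs only where the summits are shifted (202793 positions, 0 of them with shift 0). Gene levels use the summit values and not the deposited fold. Directions of called positions follow the deposited fold, and the summit values give the other direction at 92 of 55242 called positions. The fuzziness score deposited by the authors gives the spread of coverage around a position. Of the 23 columns, 6 were not used.

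The headers call the tracks treat and control and name no genotype. The deposited table is named for 2 tracks in the order d1, d2, the labels tie d1 to wild type and d2 to atrx-1, and the deposited folds are treat over control. The treat track was therefore read as wild type and the control track as atrx-1. This reading was made after the ATRX values had been seen, so ATRX is no independent check of it, and if it is the wrong way round every direction given here reverses. Ratios are given as atrx-1 over wild type.

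Because each genotype has 1 track, there is no replicate error and no test of the genotypes; a deposited false discovery rate compares these 2 tracks, not the genotypes. Depth is unknown. The values still keep steps. Within 0.001 of a step, 100% of the wild-type summit values were whole multiples of 1 step of 4.54, and 100% of the atrx-1 values were sums of whole multiples of 2 steps, 1.41 and 2.43. The atrx-1 track is thus a mean of 2 components, A and B, that hold about equal shares (49.5% in A) and were read back at every position. Components A and B cannot be tied to replicate labels. The single step of the wild-type track could come from 1 library, from libraries merged before scaling or from 1 library counted more than once. A position held on average 97.9 steps in A, 58.0 in B and 65.8 in the wild-type track (nuclear positions with signal under 900 in both tracks), so B is the noisier component. The difference between A and B is used here as a gauge of spread, and 95% intervals of medians (order statistics, binomial) cover only the spread over genes or positions.

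Genes came from a RefSeq table of assembly TAIR10.1, whose name differs from the build in the labels; none of its coordinates are printed, and positions are those of the deposited table. Mean signal was 328 at 500 bp from gene edges and 257 at the edges, with its lowest value at the edge in 15 of 15 chromosome segments, so genes were assigned by position. All 201 genes of the lists matched. A gene's level was the mean summit signal over positions centred in it, for genes with at least 3 positions: 32915 nuclear genes, of which 26509 were protein-coding with a median of 13 positions. Differences were log2((atrx-1 + 1)/(wild type + 1)), with pseudocount 1, and genes past 1.5-fold were counted. Of genic positions, 2.98% lay in 2 or more genes and count for each. The reference gives no strand, so the profile is by flanks of 1 kb, outer and middle parts of the gene. It gives no descriptions or transposable element class, so a list of ribosomal protein genes was not run and pericentromeres were taken as 2 Mb on either side of the 1 Mb run of 100 kb bins with the fewest protein-coding genes.

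The tests, gene lists, the rule for named genes and the alternatives not listed below as added were fixed before the data were examined. The rule named ATRX, the 10 highest and 10 lowest protein-coding genes with at least 5 positions, a mean at or above the median gene and at least 80% of positions on the gene's side, the 2 highest and 2 lowest members of each list, and every H3.3 gene. The 11 lists were genes for H3.3, H3.1, histone chaperones, photosynthesis, housekeeping, abiotic stress, defence, Polycomb-silenced development, DNA damage response, root-expressed genes and seed storage. A list's median was placed among 10000 random lists of protein-coding genes matched on mean level in 20 bins, as a description of these tracks. The median protein-coding gene stood at -0.11, a shift that scaling alone could set, so changes are also given relative to it. The alternatives for named genes (pseudocount 10, point columns, centring, each component), gene lists with 1 kb on both sides, the component split, limma on the components (an added setting, with 1 residual degree of freedom and a lone wild-type value assumed to vary like the components), the outer segments of chromosomes 2 and 4 and the break within ATRX were chosen after seeing the data.

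Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1. The procedures were first tested on simulated data. Of 20000 simulated sums of the 2 steps, 100% were decoded. In a simulation of this comparison with counting noise only, 100% of 67 genes lowered 1.75-fold passed 1.5-fold, as did 0.00381% of 26280 genes left alone. In the same simulated values, 3% of 200 random lists of 20 genes fell outside the central 95% of matched lists. Of 100 lists lowered by 0.1, 100% fell below it. The real spread is wider than counting noise. Between components A and B, 10 lower and 6 higher of 26509 protein-coding genes passed 1.5-fold.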

Results

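The data describe where eH3.3, a FLAG-tagged form of the replacement histone H3.3, sat in the genome of wild-type and atrx-1 plantlets. ATRX is a chromatin remodeller linked to H3.3 deposition, and the comparison asks whether its loss changes H3.3 occupancy. The labels list 2 samples of each genotype but the deposited values give 1 track per genotype, and these tracks were compared over 720055 positions, of which 716900 lie on the 5 nuclear chromosomes, 922 on the chloroplast genome and 2233 on the mitochondrial genome. Which track is atrx-1 was read from the order of names and not from a header; were it the other way round, every direction below would reverse. The atrx-1 track splits into components A and B, which gauge its spread; the wild-type track does not split. The values hold no separate replicates, so differences between the genotypes could not be tested against replicate spread.

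ATRX (AT1G08600), the mutated gene, had 59 positions between 2723892 and 2733582 on chromosome 1 (TAIR10). Its mean signal was 233 in the atrx-1 track and 329.7 in the wild-type track, a log2 difference of -0.50, and stood at 227 in component A and 239 in component B. The difference was not even along the gene. Over the first 9 positions, up to 2725237, signal was higher in the atrx-1 track (338 against 229, log2 0.56). From 2725372 on, 49 of 50 positions were lower (214 against 348, log2 -0.70; -0.74 in A and -0.65 in B). This division of the gene was chosen after its values were seen. In the authors' deposited table, 27 of these 50 positions were lower and 0 higher at a false discovery rate under 0.05, and 3 of the first 9 were higher. ATRX was the 59th lowest of 26509 protein-coding genes.

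**Figure D1:**
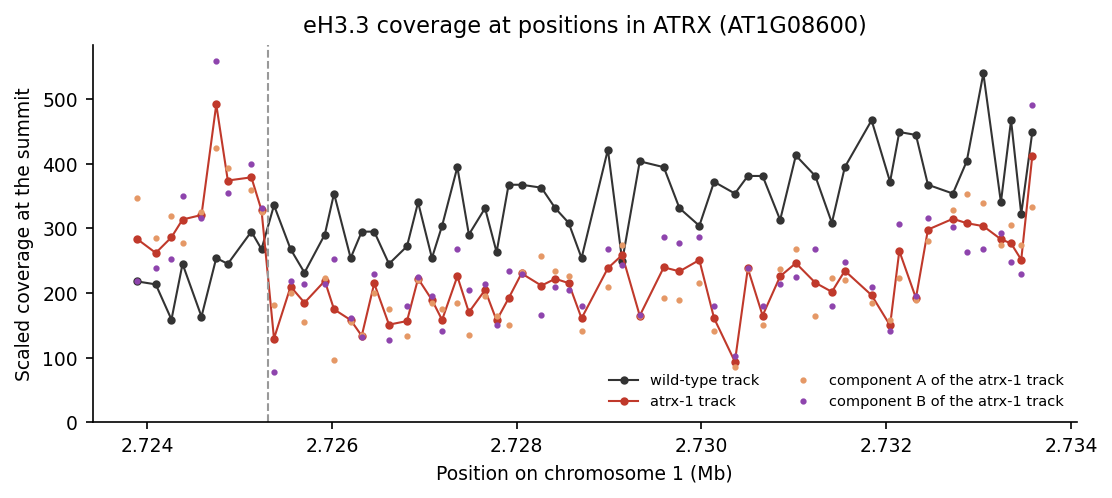
Scaled coverage at the summit of each of the 59 positions in ATRX against position on chromosome 1 in Mb, for the wild-type track, the atrx-1 track and the components A and B of the latter. The dashed line marks the division between the first 9 positions, where the atrx-1 track is higher, and the other 50, of which 49 are lower.

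Gene bodies carried slightly less eH3.3 signal in the atrx-1 track, as did chromosome arms as a whole (-0.11). Scaling alone could set such a shift. The median protein-coding gene stood at log2 -0.11 (95% interval -0.11 to -0.11 over 26509 genes), and 22324 genes (84.2%) were below 0. Against the wild-type track, the median was -0.13 in component A and -0.088 in component B. Few single genes stood far from it. Across all 32915 nuclear genes, 37 were at least 1.5-fold lower and 20 at least 1.5-fold higher, and 17 and 7 of these passed 1.5-fold in both components. Both counts depend on the processing: the higher genes numbered 1 without genes under the 10th percentile of signal and 4 with at least 5 positions, and the lower genes 135 with the median of summit values. Of the lower genes 29 of 37 were protein-coding, close to the share among all genes measured (26509 of 32915), among them UNE1, WRKY15, HSF4 and DEAR2, named after their values were seen, and 7 were long non-coding RNA genes, a class with 1376 of the 32915. WRKY15 and DEAR2 fell short of 1.5-fold in component B (-0.57 and -0.52). Of the higher ones 12 of 20 were pseudogenes, a class with 3726 of the 32915 genes, and the median signal of the higher genes was 116. The 4 protein-coding genes among the higher were AT2G07775, AT2G07738 and AT2G07835 on chromosome 2 and AT1G36020, all at or below 147 in the atrx-1 track. Over wild type, the log2 SD of protein-coding genes was 0.12 for the atrx-1 track, 0.12 for component A alone and 0.13 for component B alone. Between components A and B it was 0.11. The atrx-1 track averages 2 components, so the single components are the closer match to A over B. The match is not full. A and B were read at the same summits, those of the atrx-1 track, and the wild-type track at its own. Summits of the tracks coincided at 70.5% of positions, so A over B lacks the spread from shifted summits. In protein-coding genes, 10 lower and 6 higher passed 1.5-fold between A and B, against 29 and 4 between the atrx-1 and wild-type tracks. Component A over wild type gave 39 and 3, and component B over wild type 46 and 17, all without centring. Centred on the median protein-coding gene, the split among all 32915 genes turned round, to 12 lower and 75 higher (7 and 16 among protein-coding genes). Centred likewise, protein-coding genes numbered 5 lower and 8 higher for A over B. They numbered 8 and 12 for A over wild type, and 16 and 36 for B over wild type.

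In the authors' deposited table, 36359 of 720055 positions were lower and 18883 higher in the atrx-1 track at a false discovery rate under 0.05 for the summit signal, together 7.67% of positions. Of these called positions in the authors' deposited table, 65.8% were lower. The counts were not centred on the median protein-coding gene, which itself stood at -0.11, a shift that scaling alone could set. The common-point columns of the authors' deposited table gave 36046 lower and 20170 higher positions.

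Along genes, the atrx-1 track showed an even difference that its components did not share. Flanks of 1 kb, outer parts and the middle of protein-coding genes all stood at a median log2 of -0.11, within 0.0015 of the median gene. Signal itself was higher further inside genes in both tracks, at 290.4 in flanks, 316 in outer parts and 348 in the middle for the atrx-1 track, and at 315, 343 and 378 for the wild-type track. The components ran opposite ways, component A over wild type from -0.11 in flanks to -0.14 in the middle and component B from -0.11 to -0.085. The even profile is thus their average, and A over B ran from -0.0061 in flanks to -0.051 in the middle.

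The difference followed occupancy. Protein-coding genes in the lowest quintile of mean signal stood at -0.023, against -0.095, -0.12, -0.13 and -0.14 in quintiles 2 to 5 (5301 or 5302 genes each). In the highest quintile the median gene had a signal of 412 in the atrx-1 track and 454 in the wild-type track, and in the lowest 219 and 225. Both components showed the trend against the wild-type track, from -0.051 to -0.17 in A and from 0.0034 to -0.11 in B. Component A over B did not, at -0.058 in the lowest and -0.055 in the highest quintile. Quintiles 2 to 4 lay between -0.045 and -0.042.

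**Figure D2:**
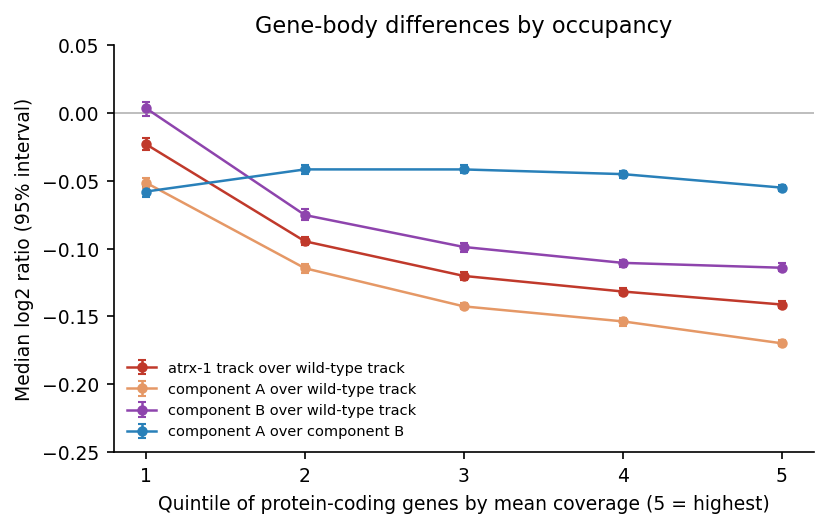
Median log2 ratio of gene-body signal (vertical axis, with 95% intervals over genes) in quintiles 1 to 5 of protein-coding genes ranked by the mean of both tracks. The atrx-1 track and both components are lower against the wild-type track where occupancy is higher, from -0.023 to -0.14 for the whole track; component A over component B stays between -0.058 and -0.042.

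Pseudogenes, a class with little eH3.3 signal, went the other way. Their median was 152 in the atrx-1 track and 142 in the wild-type track, log2 0.089 (95% interval 0.083 to 0.095, 3726 genes), or 0.20 relative to the median protein-coding gene. The difference was 0.029 in component A and 0.14 in component B. The pseudogene class is as the reference labels it. The reference has no transposable element class, so whether transposable element genes count among the pseudogenes was not checked. Class was not separated from place on the chromosome. Pericentromeric positions stood at 0.037, and most of the pseudogenes more than 1.5-fold higher lay in the pericentromeres. Long non-coding RNA genes (-0.11, 1376 genes) and other non-coding RNA genes (-0.10, 594 genes) stood with protein-coding genes. Transcribed pseudogenes (-0.057, 708 genes) and intergenic positions (-0.083, 254877 positions) were lower in the atrx-1 track as deposited but 0.053 and 0.027 above the median gene. For intergenic positions the components disagreed on the latter: A stood at -0.072 against -0.13 for its median protein-coding gene, and B at -0.10 against -0.088. These measures are unlike, since the intergenic value is a median over positions and the gene value a median over gene means. Arm positions stood at -0.12 in A and -0.10 in B. Against them, intergenic positions were higher in A and level in B. The 2 annotated rRNA genes stood at 0.50.

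Repeats and organelle DNA were higher in the atrx-1 track. The 45S rDNA, the tandem genes for ribosomal RNA, had a median signal of 67036 in the atrx-1 track and 46576 in the wild-type track over 47 positions, log2 0.49 (95% interval 0.48 to 0.52), with 0.43 in component A and 0.57 in component B, and all 47 positions were higher. Pericentromeric positions stood at 0.037 (121671 positions) and chromosome arms at -0.11 (592256 positions). Component A alone put the pericentromeres at -0.00049. The bounds of the pericentromeres follow gene density only. Of 988 windows of 100 kb outside them, 19 stood above 0, 8 of them on distal chromosome 2. Others lay shortly before the pericentromere of chromosome 2, which was set to start at 3 Mb, at 0.058 to 0.13. The chloroplast genome, which has no histones and so shows background, had 591 against 495 (log2 0.26; 0.10 in A and 0.40 in B), and the mitochondrial genome 147 against 123 (log2 0.19; 0.080 in A and 0.30 in B). Positions within 50 kb of chromosome ends had a median of -0.080 (2926 positions), but 3 of the 10 ends stood apart. The first end of chromosome 2, next to rDNA, was at 0.33, the last end of chromosome 2 at 0.10 and the last end of chromosome 4 at -0.36. The other 7 lay between -0.15 and -0.061.

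**Figure D3:**
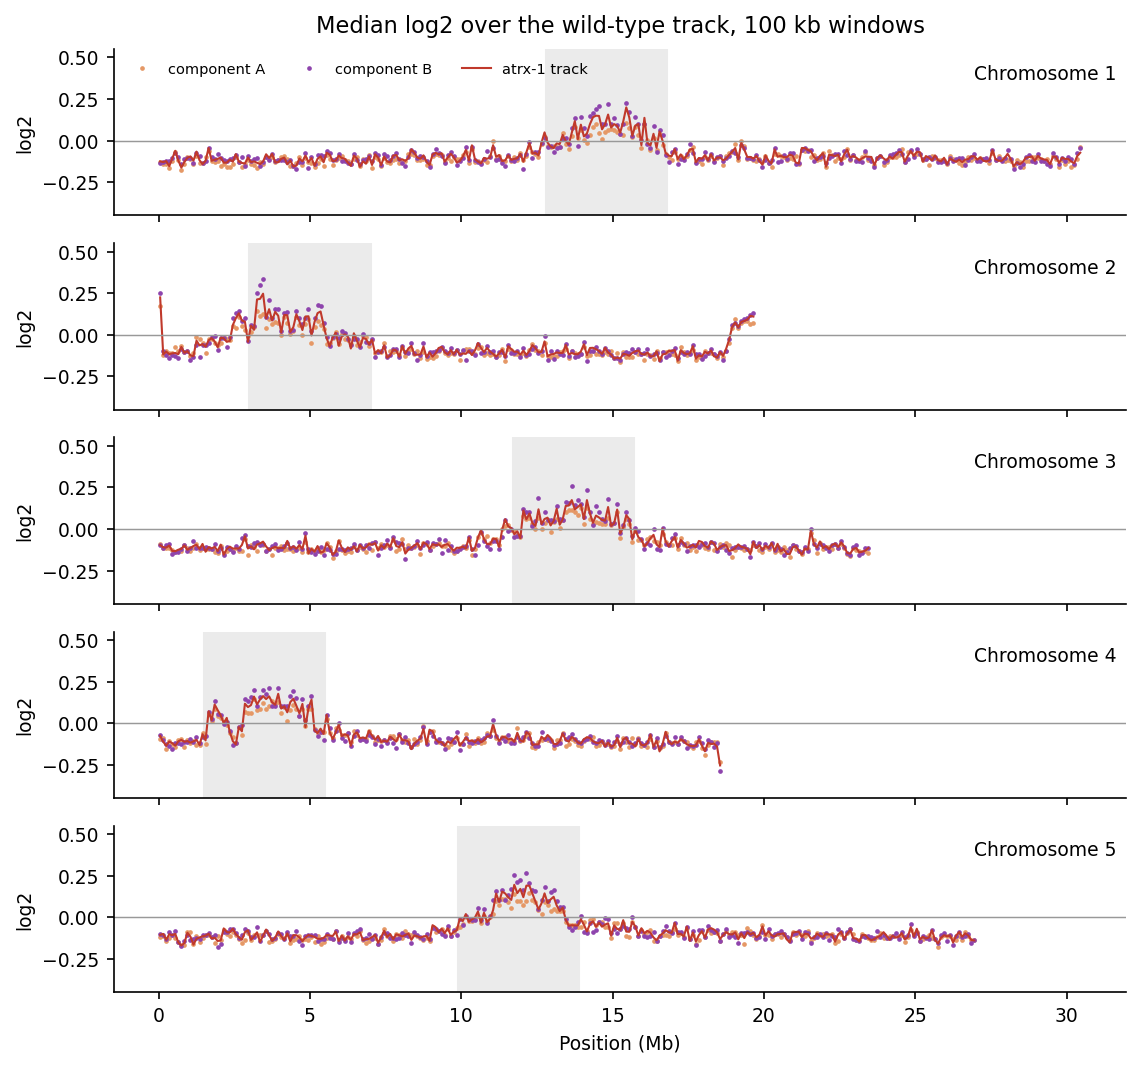
Median log2 over the wild-type track in 100 kb windows along the 5 nuclear chromosomes (position in Mb), for the atrx-1 track (line) and its components A and B (points); grey marks the pericentromeres. Arms lie near -0.11, pericentromeres above them, the distal part of chromosome 2 above 0 and the last window of chromosome 4 at -0.25.

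Of the gene lists, photosynthesis genes were lowest and root-expressed genes highest by gene body, and all 11 medians lay within the central 95% of matched random lists. The order depended on the span taken: with 1 kb added on both sides, root-expressed genes stood at -0.085 (percentile 32.4), below the H3.1 genes at -0.066, and photosynthesis genes lay outside the central 95% (percentile 1.90). Photosynthesis genes stood at -0.16 (34 genes; percentile 5.52), with 23 below the median gene, 19 of them below it in both components and 7 above it in both. Within the atrx-1 track the same list separated component A from B (-0.11, percentile 0.02), so its place between genotypes is no further out than its place between components. Relative to the median gene, the ferredoxin gene FD2 was at -0.19 and the photosystem II gene PSBR at -0.18, against 0.11 for the Rubisco small subunit gene RBCS1A and 0.24 for the photosystem I gene PSAH2. Housekeeping genes stood at -0.15 (19 genes; percentile 26.9), with the elongation factor gene EF1A4 at -0.16 and the ubiquitin gene UBQ10 at -0.14 relative to the median gene, and the actin gene ACT8 at 0.038 and UBQ5 at 0.13. As deposited, ACT8 was lower in the atrx-1 track, at -0.072.

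Stress and defence genes lay close to their random lists. Abiotic stress genes stood at -0.13 (27 genes; percentile 9.81, or 46.0 with 1 kb on both sides). Among them the cold-response factors CBF2 and CBF1 were at -0.23 and -0.15 relative to the median gene, COR15B at 0.088 and the dehydrin ERD14 at 0.30. Over wild type, ERD14 stood at 0.037 in component A and 0.33 in component B. Defence genes stood at -0.13 (20 genes; percentile 28.4), from the defensin PDF1.2 (-0.27) and WRKY33 (-0.20) to the resistance gene RPS2 (0.11) and PR1 (0.18). DNA damage response genes stood at -0.075 (20 of 21 genes measured; percentile 82.4), but at percentile 15.7 with 1 kb on both sides. The ribonucleotide reductase gene TSO2 was the 107th lowest protein-coding gene, at 154 in the atrx-1 track and 210.1 in the wild-type track (-0.34 relative to the median gene), and KU70 was at -0.083, RAD17 at 0.10 and the mitotic cyclin CYCB1;1 at 0.22.

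Polycomb targets and flowering regulators, root-expressed genes and seed storage genes lay within their random lists, whose medians were also above the median gene (-0.070, -0.065 and -0.098). The Polycomb targets and flowering regulators stood at -0.070 (25 genes; percentile 50.5), with LEC1 at -0.15 and FLC at -0.049 relative to the median gene and the floral genes SEP3 and PI at 0.19 and 0.20. Root-expressed genes stood at -0.019 (17 genes; percentile 92.1), with 5 of 17 below the median gene. PLT2 and the iron transporter IRT1 were at -0.12 and -0.068 and the phosphate transporter PHT1;1 and CASP1 at 0.22 and 0.25. Seed storage genes stood at -0.082 (11 genes, percentile 68.9), from EM6 (-0.22) and CRU3 (-0.042) to SESA2 (0.088) and CRA1 (0.16). The components disagreed on 2 of these relative to their median protein-coding gene (-0.13 in A, -0.088 in B). CRU3 stood above it in A (-0.032) and below it in B (-0.285). SESA2 stood slightly below it in A (-0.145) and above it in B (0.090).

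Histone chaperone genes stood at -0.13 (19 genes; percentile 46.2, or 92.8 with 1 kb on both sides). ATRX and ASF1B were lowest, at -0.39 and -0.16 relative to the median gene, and NAP1;2 and the chromatin assembly factor gene FAS1 were highest, at 0.053 and 0.094; as deposited both of the latter were lower in the atrx-1 track. The H3.1 genes stood at -0.027 (5 genes, percentile 96.7), with HTR9 at -0.065 and HTR13, HTR1 and HTR2 at 0.066, 0.11 and 0.16 relative to the median gene. Against each component's median gene (-0.13 in A, -0.088 in B), HTR9 was lower in A (-0.30) but higher in B (-0.059). HTR1 was higher in A (0.096) and slightly lower in B (-0.10). The H3.3 genes stood at -0.14 (3 genes; percentile 23). HTR8 had 282 in the atrx-1 track and 323 in the wild-type track, 1452 and 1601 were read at HTR5, and HTR4 was close to empty at 6.75 and 6.05. Reads at the H3.3 genes are uncertain, since a tagged copy can share their sequence.

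**Figure D4:**
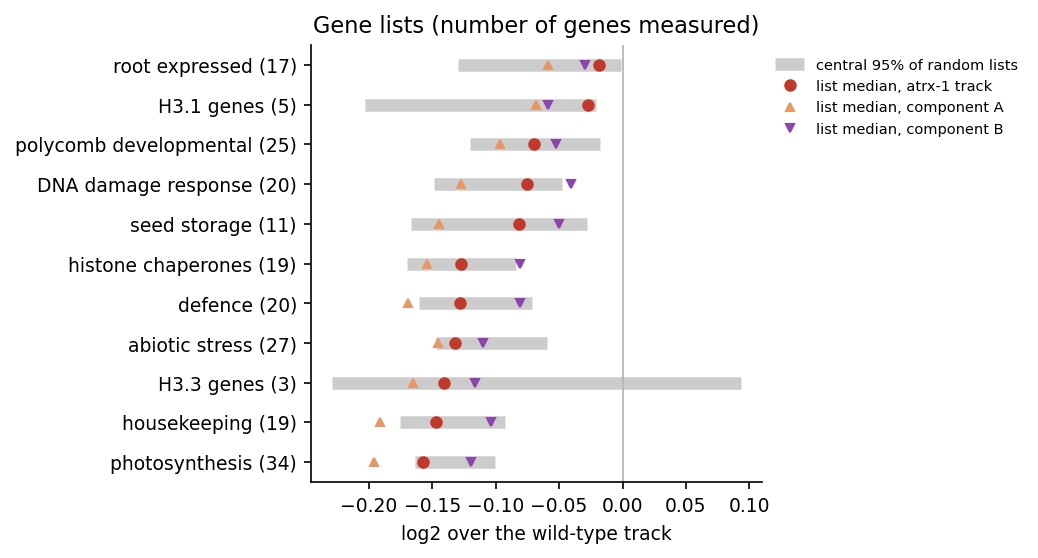
Median log2 over the wild-type track of each gene list (horizontal axis) for the atrx-1 track and its components A and B, with the central 95% of 10000 matched random lists for the atrx-1 track in grey and the number of genes measured in parentheses. All 11 medians of the atrx-1 track lie inside the grey bars, from -0.16 for photosynthesis to -0.019 for root-expressed genes.

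The 10 lowest well-covered genes, with at least 90.9% of positions lower, were ICK5, a cyclin-dependent kinase inhibitor gene, LBD26, AT4G38490, AT5G49560, AT3G18950, the auxin-responsive SAUR9, TIM8, RLP55, the ubiquitin ligase gene NLA and AT2G43730. They ran from -0.50 at ICK5 (339 in the atrx-1 track, 478 in the wild-type track, 337 and 340.1 in the components) to -0.41 at AT2G43730 (323 and 430.3). The 10 highest fell into few places. AT3G41762, AT2G01008, AT2G08986 and AT1G40104 had signals from 21136 to 85493 in the wild-type track, which marks sequence present in many copies, and log2 differences from 0.22 to 0.40. AT2G01008 lies at the first end of chromosome 2, next to rDNA. AT2G01008 and AT3G41762 had 49942.5 and 85493 in the wild-type track, against a median of 46576 at the rDNA. Whether these genes are part of the rDNA repeat was not tested. GulLO6, SDR5, AT2G47670, PAC and AT2G47500 lie on distal chromosome 2, between 19212962 and 19681492, at 0.22 to 0.35. GulLO6, the highest of them, had 395 against 310.3, with log2 0.20 in component A and 0.48 in component B. AT1G38790 stood at 0.29.

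More positions were fuzzier than less fuzzy in the atrx-1 track. In the authors' deposited table, 41999 positions were fuzzier and 19128 less fuzzy in the atrx-1 track at a false discovery rate under 0.05. The median fuzziness score in the authors' deposited table was 59.6 in the atrx-1 track and 59.0 in the wild-type track. Summits of the tracks coincided at 70.5% of positions in the authors' deposited table, and 9.11% were over 50 bp apart. How far the pooling of 2 components, or a difference in depth, sets these scores was not tested.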

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

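Settings named here as added (components, limma, segments, 1 kb on both sides of list genes, and every setting applied to the named genes) were chosen after seeing the data. No paired analysis was possible because the columns hold 1 track per genotype and no replicate. The upstream-to-end variant of the gene lists was not run, as the reference has no strand. Read depth is not given, and steps per position (97.9 in A, 58.0 in B, 65.8 in the wild-type track) are the only gauge of it. How far this imbalance moves the fold counts and the deposited calls was not tested. The deposited calls fell from 36359 lower and 18883 higher positions to 7855 and 5148 at a false discovery rate under 0.01, and the fuzziness calls to 4703 lower and 11617 higher. Genes past 1.5-fold (37 lower, 20 higher) became 12 and 75 with centring, 254 and 147 with at least 1 position, 20 and 4 with at least 5 positions, 135 and 68 with the median of summit values, and 1 and 0 at 2-fold. Higher genes numbered 13 with pseudocount 10 and 1 without genes under the 10th percentile of signal. Added settings gave 62 lower and 13 higher genes with component A alone, 79 and 79 with component B alone, 1103 and 59 with limma on the components, and 0 and 0 with limma after centring. The limma counts carry no weight for the genotypes, because the wild-type value has no spread of its own and the calls go with the offset that scaling can set. The median protein-coding gene (-0.11) moved to -0.11 with pseudocount 10, 0 by construction with centring, -0.10 with point columns, -0.10 with the median of summit values, -0.11 without genes under the 10th percentile, -0.13 with component A and -0.088 with component B. Flanks, outer parts and middle stood at -0.10, -0.10 and -0.10 with point columns, and at -0.096, -0.10 and -0.10 in genes with no neighbour within 1 kb. Centring turned transcribed pseudogenes (0.053), other non-coding RNA (0.0086) and intergenic positions (0.027) positive, and put protein-coding genes at 0, pseudogenes at 0.20, long non-coding RNA at -0.0017 and rRNA genes at 0.61. Pseudocount 10 gave -0.080 for intergenic positions. Quintiles 1 and 2 stood at -0.028 and -0.097 when ranked within gene length, and quintiles 1 to 5 at -0.0095, -0.086, -0.12, -0.13 and -0.14 with point columns. With point columns, pericentromeres stood at 0.057, arms at -0.10 and the mitochondrial genome at 0.23. With ends taken as 200 kb (summit values), chromosome ends stood at -0.098. With 1 kb on both sides, chaperone genes had a median of -0.10 (percentile 92.8, from 46.2), abiotic stress genes went from percentile 9.81 to 46.0, and photosynthesis genes passed below the central 95% of random lists (percentile 1.90). With the same span root-expressed genes stood at -0.085 (percentile 32.4), no longer highest, and DNA damage genes went from percentile 82.4 to 15.7. With point columns the root-expressed median changed sign, to 0.0082. In the settings added for the 63 named genes, HTR13 (0.066), FAS1 (0.094) and ACT8 (0.038) have the same sign in both components and changed it with centring. Counting every gene, 8 changed sign with centring, among them NAP1;2 (0.053), COR15B (0.088), RPS2 (0.11), RAD17 (0.10) and SESA2 (0.088). Component A alone changed the sign of 7, including HTR4 (-0.56) and CRA1 (-0.10), component B alone of 6, including PR1 (-0.034), and point columns of 2, HTR2 (-0.024) and SESA2 (0.064). Centring shifts every log2 value alike. Why the other values moved was not tested. The component tallies use values that are not centred, so they do not count CRU3, HTR9 and other genes that change side of a component's median gene.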

Other observations

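The tests on distal chromosomes 2 and 4 and of the ranking and matching of genes were fixed before their results were seen; the tests on the chloroplast signal, on high-copy sequence, on the middle tercile of positions and on weighted bins of pseudogenes were chosen after, and all patterns were found in these data. The H3.3 genes HTR4 and HTR5 lie side by side near the end of chromosome 4, in a near-empty stretch and a high stretch that both run past the genes in both tracks. At HTR4, 3 positions had signals between 0 and 9.08 in the wild-type track and between 0 and 20.3 in the atrx-1 track. At HTR5, 9 positions reached 2541 and 2559, with a fall to 113 in the wild-type track and 33.2 in the atrx-1 track at the position of lowest signal. The next 4 positions, from 18559362 to 18559872, were as high, at up to 2391 and 2262, and the position before HTR4, 18555422, was as empty as HTR4 (9.08 and 0). Of the 4 protein-coding genes more than 1.5-fold higher in the atrx-1 track, AT2G07775, AT2G07738 and AT2G07835 lie between 3483127 and 3502122 on chromosome 2, inside the stretch of mitochondrial DNA that this chromosome is known to carry.

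An outer segment of chromosome 2, from 18860162 to 19698167 (838 kb, 240 protein-coding genes), was higher in the atrx-1 track by 0.19 over chromosome arms (0.18 in component A, 0.19 in B). The last 24.9 kb of chromosome 4, from 18560032 on, stood at -0.35 relative to them (-0.29 in A, -0.47 in B). A few loci did not carry the first segment, since 84 of 84 bins of 10 kb (100%) lay above the median arm bin. A difference in DNA copies between the lines may account for both but is left open. It needs like excess at every occupancy. In component A the highest minus the lowest tercile of positions was 0.024 on chromosome 2 and 0.041 on chromosome 4. Both lay within the limits set beforehand for like excess. In component B the chromosome 2 value was 0.047 (95% interval 0.0072 to 0.085). The middle minus the lowest on chromosome 2 was 0.048 in A (0.015 to 0.082) and 0.091 in B (0.047 to 0.13). The highest minus the middle ran the other way there, at -0.024 in A and -0.044 in B (-0.070 to -0.013). On chromosome 4 the middle minus the lowest was 0.13 in A (-0.039 to 0.27) and 0.0083 in B, over only 5 bins of 5 kb. The size of the excess was not set against any number of copies. A change of H3.3 over each segment stays open as well, and no mutant input was analysed here.

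The trend of gene-body differences with occupancy (-0.12 from the lowest to the highest quintile) was not made by ranking genes on the values compared. With genes ranked on component B, component A over wild type still gave -0.097. Background DNA marked by the chloroplast signal is argued against only for the span from the lowest to the highest quintile. The components differ in chloroplast signal by -0.31 but over that span by 0.0029. The span hides a rise and a fall. Component A over B rose from -0.058 in quintile 1 to -0.042 in quintile 2, the way such background would go. It fell to -0.055 by quintile 5. Background thus stays open for the step from quintile 1 to 2. The test covers protein-coding genes only. Component A over B was -0.11 in pseudogenes against -0.048 in protein-coding genes, and -0.061 in pericentromeres against -0.016 in arms. Intergenic positions went the other way, at 0.031. Whether background sets the pseudogene and pericentromere values was not tested. Lower enrichment over nuclear background in both mutant libraries may explain the trend but is left open. Pseudogenes and protein-coding genes of like occupancy should then move alike. Over bins they differed by a median of 0.038 in component A and 0.042 in B, within the limit set beforehand for moving alike. Pseudogenes were still higher in 9 of 10 and 8 of 10 bins. In the lowest bin of B, which holds 1443 of 2654 pseudogenes, the difference was 0.087. Means weighted by pseudogenes, added later, were 0.037 in A and 0.064 in B. The bins matched occupancy but not place on the chromosome. A loss of H3.3 in atrx-1 that scales with occupancy also stays open and is untested.

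The excess at the 45S rDNA went beyond that of other high-copy sequence. It exceeded the 654 other nuclear positions with over 10 times the median signal by at least 0.28 in each component, and the chloroplast genome by at least 0.17 in each, so neither a general rise of repeats nor background DNA marked by the chloroplast accounts for all of it. The rDNA was taken as the annotated rRNA genes and the positions close around them. Sequence of the same repeat farther out may therefore count among the 654. More rDNA copies in the mutant line or more H3.3 per copy could each give the excess at the rDNA, and no value here separates them.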
